A study of Mus musculus with 9 samples.

How the data were processed

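The series measured RNA of mouse spinal cord after complete transection at T9, at 0, 3 and 21 days. Per the labels' protocols, messenger RNA was selected by its poly-A tail, fragmented and made into paired-end TruSeq libraries for an Illumina NovaSeq instrument. The submitters' processing notes name HISAT2 and StringTie without versions, and they name the human build GRCh38 although the organism is mouse. The gene loci in the table are those of mouse build GRCm38, and of 34344 gene IDs also in GENCODE M21, 27776 had the same chromosome, start and end. The aligner settings, the annotation used and the use of strand in counting are not given in the sources used here.

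The titles put 3 libraries in each of 3 groups. The day 3 and day 21 groups carry their day in the title, and the remaining group was taken as day 0, since the series design names 0, 3 and 21 days. The length of cord taken is not given in the sources used here, and no source used here says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

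The deposited table holds 1 count column and 1 FPKM column per library for 34745 genes. The counts are whole numbers per gene, not normalized, per the file headers and the values. The deposited FPKM values equal count divided by gene length and by the library's own total, with a deviation of at most 0.00117% between libraries over 12001 genes with at least 50 counts in every library. The most abundant gene, mt-Co1, took 2.62 to 3.72% of counts and mitochondrial-encoded genes 6.93 to 10.9%. Ribosomal protein genes took 0.527 to 1.33%, the highest in day 21 replicate 2.

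Groups were compared on the counts with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its default expression filter and robust quasi-likelihood fits. All 9 libraries entered 1 fit, with 6 residual degrees of freedom and a common biological coefficient of variation of 0.205. The design written before the data were examined named limma on log2(FPKM + 1) as the main test unless the table held counts, in which case edgeR was to be the main test, and it does hold them. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and is given as edgeR adjusted p. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. FPKM values are mean ± SD over 3 libraries. Folds against a group without counts use a floor of 3 counts summed over the group, and ratios on 1 to 3 counts carry an exact 95% binomial interval.

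Before the data were examined, 56 gene lists with 1130 entries and 1031 distinct genes were fixed from textbook knowledge of cord cell types, injury responses and cell death, and 55 had at least 5 tested members. Of the entries 1126 matched by symbol and 4 by gene ID. In bulk tissue the cell type lists describe marker transcripts, not cell numbers. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists, given as camera adjusted p, and again with the correlation estimated per list. Of the list calls in the report, those without an adjusted p for an estimated correlation hold with it. Lists of sensory neuron, leukocyte and further muscle genes were written later, before their values were seen. Counts of members adjusted over the list alone are given where they differ from those over all genes.

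Named genes followed a rule written before the data were examined. It took the 6 highest and 6 lowest log2 fold changes per comparison among called genes with a mean of at least 5 FPKM in the higher group, leaving out unnamed, ribosomal, haemoglobin, mitochondrial and antigen receptor genes. It added up to 4 called members at 1 FPKM or more with the largest changes of each list described, all PANoptosis core genes and the tissue markers. The text names up to 2 of the 4 for the lists it describes by genes, and other lists by count and median. Exon overlap was checked for 246 genes on GENCODE M21, and 88 overlapped another gene, 17 of them over more than 20% of exon bases. Some genes that the rule took are not reported here. Near-identical copies and overlapping genes are reported as uncertain.

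The alternatives, planned for FPKM values and applied to the counts where the method allowed, were DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 0.1, 1 and 5, TPM, median-of-ratios and quantile scaling, no filter and a filter of 5 FPKM in 3 libraries, non-robust fits, a fit of only 2 groups, limma voom with sample weights, the replicate number as a block, and each library left out in turn. Removal of a gene-length trend was added after seeing the data. On simulated counts with the real means and library sizes, edgeR recovered 5.97% of 67 genes changed 1.5-fold, 49.3% of 67 changed 2-fold and 84.8% of 66 changed 4-fold for day 3 against day 0, and 2.99%, 31.3% and 84.8% for day 21 against day 0. Unchanged genes made up 4.07% and 3.66% of the calls, over 16263 genes tested. A raised lysosome list was recovered and 0 of 54 other lists was called by camera. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.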

Results

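RNA was sequenced from mouse spinal cord in a series on complete transection at T9. The 3 groups were day 0 (titled N, not explained), day 3 and day 21, with 3 libraries each. No sham group separates injury from surgery. Total gene counts per library were 24022923, 15763769 and 17616197 at day 0. They were 16096659, 17930431 and 14916863 at day 3, and 15756253, 14543802 and 14299679 at day 21. Of 34745 genes in the deposited table, 23736 had a count in at least 1 library and 16494 were tested.

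The days separated on the first 2 principal components, which held 59.6% and 16.8% of the variance. Within groups log2 CPM of library pairs correlated at 0.983 to 0.987 at day 0 and 0.985 to 0.987 at day 3. By sample weight day 0 replicate 1 stood apart (0.354 against 1.75 and 2.03). At day 21 replicates 1 and 3 correlated at 0.985, and replicate 2 with them at 0.941 and 0.932. Day 21 replicate 2 lay at 46.8 on component 3 (11.5% of the variance), with the other day 21 libraries at -42.7 and -53.0. In that library the median difference from the other day 21 libraries was 1.07 log2 units for nuclear genes of oxidative phosphorylation, 0.75 for MHC class II, 0.65 for neutrophil and 0.63 for skeletal muscle genes, and -0.73 for ion channels and -0.41 for synapse genes. No 2 libraries were identical.

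**Figure D1:**
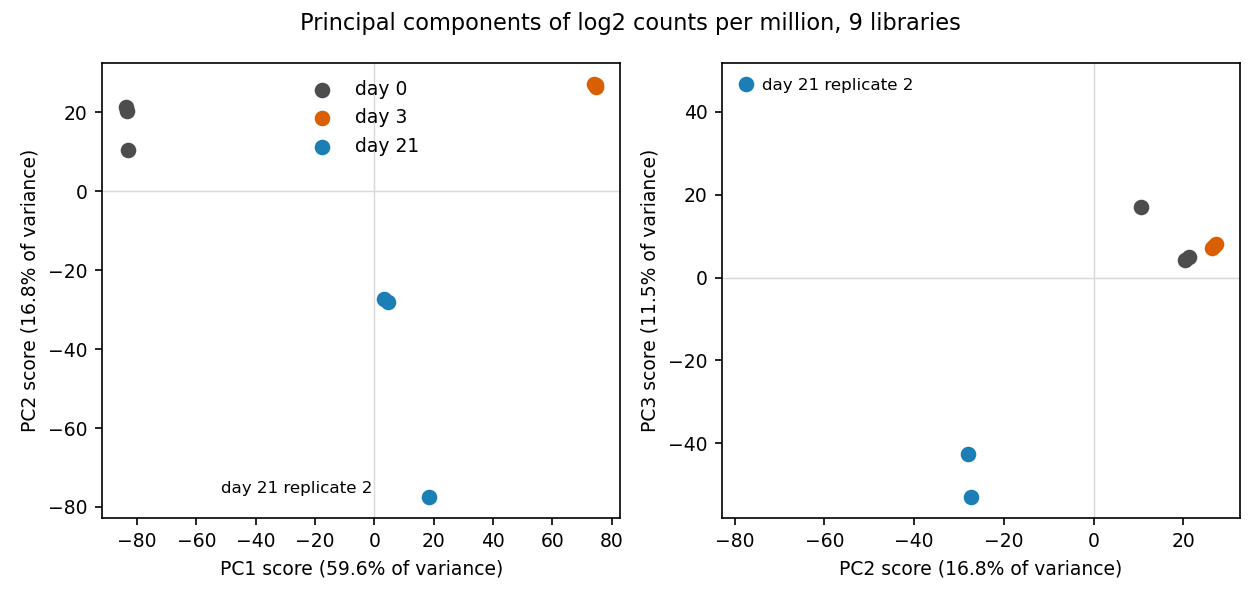
Principal components of log2 CPM over the 16494 tested genes, with component 1 against 2 (left) and 2 against 3 (right), axes in score units. Each point is 1 library (day 0 grey, day 3 orange, day 21 blue, 3 each), and day 21 replicate 2 lies at -77.5 on component 2, where the other day 21 libraries lie at -28.0 and -27.4.

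The comparison of day 3 with day 0 asked which transcripts differed early after transection. Myeloid, cell division, scar matrix, reactive glial and Schwann cell genes were higher at day 3, and pan-neuronal and inhibitory neuron genes were lower. All 25 tested monocyte and macrophage genes and all 28 collagen and fibrotic matrix genes rose, with median log2 fold changes of 4.32 and 3.54 (camera adjusted p 1.43e-33 and 2.56e-66). Of 20 pan-neuronal genes 19 fell, with a median of -1.02 (camera adjusted p 1.28e-09).

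Among myeloid genes, the pattern recognition receptor Clec4d was at least 151-fold higher, from 0 counts at day 0, and the acute phase gene Saa3 was 736-fold higher (counting interval 203 to 6087). Such bounds and intervals cover counting error only. Genes of lipid-laden phagocytes rose together (29 of 29 higher, median 3.0, camera adjusted p 1.13e-39). Their scavenger receptor Msr1 rose from 0.0540 ± 0.0112 to 7.96 ± 0.249 FPKM (mean ± SD), with log2 fold change 7.15 ± 0.19, edgeR adjusted p 5.12e-08. The proton pump subunit Atp6v0d2 was 234-fold higher (counting interval 64.3 to 1938). Cytokine and chemokine genes were higher at day 3 (26 of 31 higher and 1 lower, median 3.45, camera adjusted p 2.83e-18). The granulocyte growth factor Csf3 was at least 109-fold higher, and Ccl2, which attracts monocytes, rose with log2 fold change 5.92 ± 0.35, edgeR adjusted p 1.77e-06. All 21 complement genes rose (median 3.03, camera adjusted p 1.62e-22). Ahead were factor B, Cfb, and the anaphylatoxin receptor C5ar1 (log2 fold changes 6.27 ± 0.45 and 5.06 ± 0.14, edgeR adjusted p 5.52e-06 and 6.12e-08). The Cfb value is uncertain, since 79.5% of its exon bases overlap another gene. Microglial genes were higher (15 of 20 higher and 1 lower, median 1.61, camera adjusted p 6.67e-08). Lysosomal genes were higher (24 of 28 higher and 1 lower, median 1.36, camera adjusted p 2.91e-16). Interferon response genes were higher (29 of 29 higher, median 1.44, camera adjusted p 1.89e-09). MHC class II genes passed only the preset correlation (10 of 11 higher, median 2.21, camera adjusted p 3.38e-05, adjusted p 0.16 with an estimated correlation). MHC class I genes passed only the preset correlation (15 of 17 higher, median 1.33, camera adjusted p 0.000338, adjusted p 0.359 with an estimated correlation). Neutrophil genes did likewise (15 of 18 higher and 1 lower, or 17 and 1 adjusted over the list alone, median 2.44, camera adjusted p 3.57e-06, adjusted p 0.0851 with an estimated correlation). T and NK cell genes did not pass the test (5 of 8 higher, or 6 adjusted over the list alone, median 1.52, camera adjusted p 0.159), except without the count filter (camera adjusted p 0.0211, over alternatives 0.0211 to 0.381).

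Cell cycle genes were higher at day 3 (29 of 30 higher and 1 lower, median 4.09, camera adjusted p 1.13e-39). The mitotic checkpoint kinase Bub1 was 187-fold higher (counting interval 51.3 to 1549), and the proliferation antigen Mki67 rose from 0.0953 ± 0.0413 to 6.85 ± 0.198 FPKM (log2 fold change 6.13 ± 0.35, edgeR adjusted p 1.61e-06). Matrix genes rose with them, among them the collagen crosslinking enzyme Lox and tenascin C, Tnc (log2 fold changes 5.40 ± 0.20 and 4.90 ± 0.11, edgeR adjusted p 1.65e-07 and 3.33e-08). Matrix protease and inhibitor genes were higher (17 of 21 higher and 1 lower, median 3.23, camera adjusted p 4.67e-20). Foremost was Timp1, an inhibitor of metalloproteases (log2 fold change 7.85 ± 0.45, edgeR adjusted p 1.64e-06). Fibroblast and meningeal genes were higher (19 of 20 higher, or 19 and 1 lower adjusted over the list alone, median 2.69, camera adjusted p 2.10e-26). Basement membrane genes were higher (13 of 14 higher, median 2.14, camera adjusted p 4.34e-16). Endothelial genes were higher (16 of 22 higher, or 17 adjusted over the list alone, median 0.91, camera adjusted p 0.000162). They included the junction cadherin Cdh5 and the sialomucin Emcn (log2 fold changes 2.85 ± 0.19 and 1.60 ± 0.14, edgeR adjusted p 3.34e-06 and 1.53e-05). Pericyte and smooth muscle genes were higher too (10 of 16 higher, or 12 adjusted over the list alone, median 0.78, camera adjusted p 2.12e-05).

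Reactive astrocyte genes were higher at day 3 (31 of 32 higher, median 2.77, camera adjusted p 1.39e-34). Ahead were Timp1 and the iron-binding lipocalin Lcn2, which rose from 0.415 ± 0.159 to 31.4 ± 3.47 FPKM (log2 fold change 6.16 ± 0.32, edgeR adjusted p 8.66e-07). All 16 Schwann cell genes rose (median 2.37, camera adjusted p 1.18e-19). These included fibulin 2, Fbln2, and the neurotrophin receptor Ngfr (log2 fold changes 5.36 ± 0.17 and 4.92 ± 0.17, edgeR adjusted p 8.89e-08 and 9.53e-08). Their summed FPKM was 193 ± 18.2 (SD) at day 0 and 737 ± 10.8 at day 3. At the same day 14 of 20 peripheral sensory neuron genes, a list written after the fixed ones, were higher by edgeR. Axon growth genes were higher (14 of 21 higher and 2 lower, or 14 and 3 adjusted over the list alone, median 0.83, camera adjusted p 2.53e-07). Ahead were Sprr1a, a small proline-rich protein of regenerating neurons, and the arginine-degrading enzyme Arg1 (log2 fold changes 9.06 ± 0.36 and 8.64 ± 0.57, edgeR adjusted p 2.19e-07 and 3.62e-06). Ferroptosis and iron genes rose (13 of 20 higher and 1 lower, median 1.23, camera adjusted p 3.33e-09). The haem-degrading enzyme Hmox1 went from 3.57 ± 0.324 to 227 ± 5.10 FPKM, and the prostaglandin synthase Ptgs2 was next (log2 fold changes 5.94 ± 0.15 and 4.94 ± 0.26, edgeR adjusted p 4.41e-08 and 9.19e-07). Immediate early genes were higher (16 of 20 higher and 1 lower, median 1.74, camera adjusted p 8.97e-13). NADPH oxidase and oxidative stress genes were higher (13 of 21 higher and 2 lower, median 1.55, camera adjusted p 4.20e-07). Cholesterol efflux genes were higher (12 of 18 higher, or 13 adjusted over the list alone, median 1.14, camera adjusted p 9.88e-10). ER stress genes were higher only with the preset correlation (10 of 18 higher and 1 lower, median 0.93, camera adjusted p 0.0113, adjusted p 0.413 with an estimated correlation).

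Inhibitory neuron genes fell (10 of 12 lower, median -1.19, camera adjusted p 1.12e-05). These included the glycine transporter Slc6a5 and the gap junction protein Gjd2 (log2 fold changes -1.92 ± 0.29 and -1.76 ± 0.15, edgeR adjusted p 0.000652 and 1.59e-05). The pan-neuronal genes that fell included the microtubule protein Map2 and the neurofilament light chain Nefl (log2 fold changes -1.80 ± 0.42 and -1.45 ± 0.08, edgeR adjusted p 0.00702 and 9.80e-07). The Nefl value is uncertain, since 32.8% of its exon bases overlap Nefm. Synapse and receptor genes were lower (24 of 28 lower, or 26 adjusted over the list alone, median -1.01, camera adjusted p 3.25e-09, adjusted p 0.136 with an estimated correlation). Ion channel genes were lower too (14 of 19 lower, or 15 adjusted over the list alone, median -1.34, camera adjusted p 1.17e-07, adjusted p 0.128 with an estimated correlation). The glycine receptor subunit Glra1 fell from 48.7 ± 6.80 to 6.59 ± 0.469 FPKM (log2 fold change -2.94 ± 0.28, edgeR adjusted p 3.73e-05). The GABA receptor subunit Gabrb2 was lower (log2 fold change -2.09 ± 0.75, edgeR adjusted p 0.0488), a call lost without any library but day 21 replicate 2 (adjusted p 0.0502 to 0.13), with limma on log2 FPKM or TPM and without the count filter (adjusted p over alternatives 7.26e-06 to 0.0986). Oligodendrocyte and myelin genes were lower at the preset correlation (12 of 26 lower and 3 higher, median -0.36, camera adjusted p 0.016, adjusted p 0.0787 with an estimated correlation). Cholesterol biosynthesis genes were lower at the preset correlation (12 of 22 lower, or 13 adjusted over the list alone, median -0.34, camera adjusted p 0.00303, adjusted p 0.0674 with an estimated correlation). Nuclear oxidative phosphorylation genes were lower at the preset correlation (7 of 36 lower, or 6 adjusted over the list alone, median -0.49, camera adjusted p 0.00303, adjusted p 0.599 with an estimated correlation). For the last list the median was -0.30 without day 0 replicate 1, and 25 genes were lower without day 21 replicate 2. Lumbosacral Hox genes fell (5 of 6 lower, median -1.34, camera adjusted p 0.00163). Ahead were Hoxd10 and Hoxc10 (log2 fold changes -2.12 ± 0.16 and -1.03 ± 0.13, edgeR adjusted p 6.55e-06 and 0.00017). Lower cervical and thoracic Hox genes were lower at the preset correlation (9 of 18 lower, median -0.58, camera adjusted p 0.00445, adjusted p 0.194 with an estimated correlation). Skeletal muscle genes were lower at the preset correlation (7 of 16 lower and 1 higher, median -0.65, camera adjusted p 0.00729, adjusted p 0.435 with an estimated correlation).

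The rule for called genes at 5 FPKM or more took as highest at day 3, by fitted change, the serine protease inhibitor Serpina3m (at least 262-fold) and the apolipoprotein Apoc2 (at least 196-fold), both without a count at day 0, so their place is not set by a measured fold. The Apoc2 value is uncertain, since 79.5% of its exon bases overlap another gene. Scn10a, a sodium channel of peripheral sensory neurons (chromosome 9, 119608456 to 119719032, build GRCm38), was 1616-fold higher (counting interval 447 to 13354), and the membrane protein Tmem233 was 789-fold higher (counting interval 218 to 6523). Saa3 and the transglutaminase Tgm1 (log2 fold change 9.09 ± 0.30, edgeR adjusted p 8.89e-08) completed the 6. The lowest were Glra1 (chromosome 11, 55514238 to 55608198), Lingo4, Chodl, a marker of fast motor neurons, Myoc, Syt2, a calcium sensor of synaptic vesicles, and Hs6st3. Their log2 fold changes were -2.94 ± 0.28, -2.80 ± 0.53, -2.72 ± 0.18, -2.35 ± 0.19, -2.30 ± 0.55 and -2.28 ± 0.78, with edgeR adjusted p from 3.71e-06 to 0.0394. The Hs6st3 call was lost without any 1 of the day 0 or day 3 libraries (adjusted p 0.0765 to 0.108), with DESeq2 and with limma on log2(FPKM + 0.1) (adjusted p over alternatives 3.98e-06 to 0.155).

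By camera 30 of 55 lists were higher and 10 lower at day 3, and 25 and 3 with an estimated correlation. Median, mean and test differed in sign for glycolysis and hypoxia (median -0.017, mean 0.28, camera adjusted p 0.638, higher), mitochondrial encoded (median 0.019, mean 0.14, camera adjusted p 0.646, lower), dendritic cell (median 0.062, mean 0.16, camera adjusted p 0.623, lower) and ependymal (median 0.23, mean 0.18, camera adjusted p 0.894, lower). Of single genes, 4090 were higher and 3217 lower at day 3 by edgeR. Without day 21 replicate 2 there were 5354 higher and 4891 lower, and with sample weights 5710 and 5215. Against limma on log2(FPKM + 1), quantile normalization shifted the median of all genes by -0.15 and TPM by -0.12, with 2851 higher and 3840 lower genes, and 2955 and 3371.

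**Figure D2:**
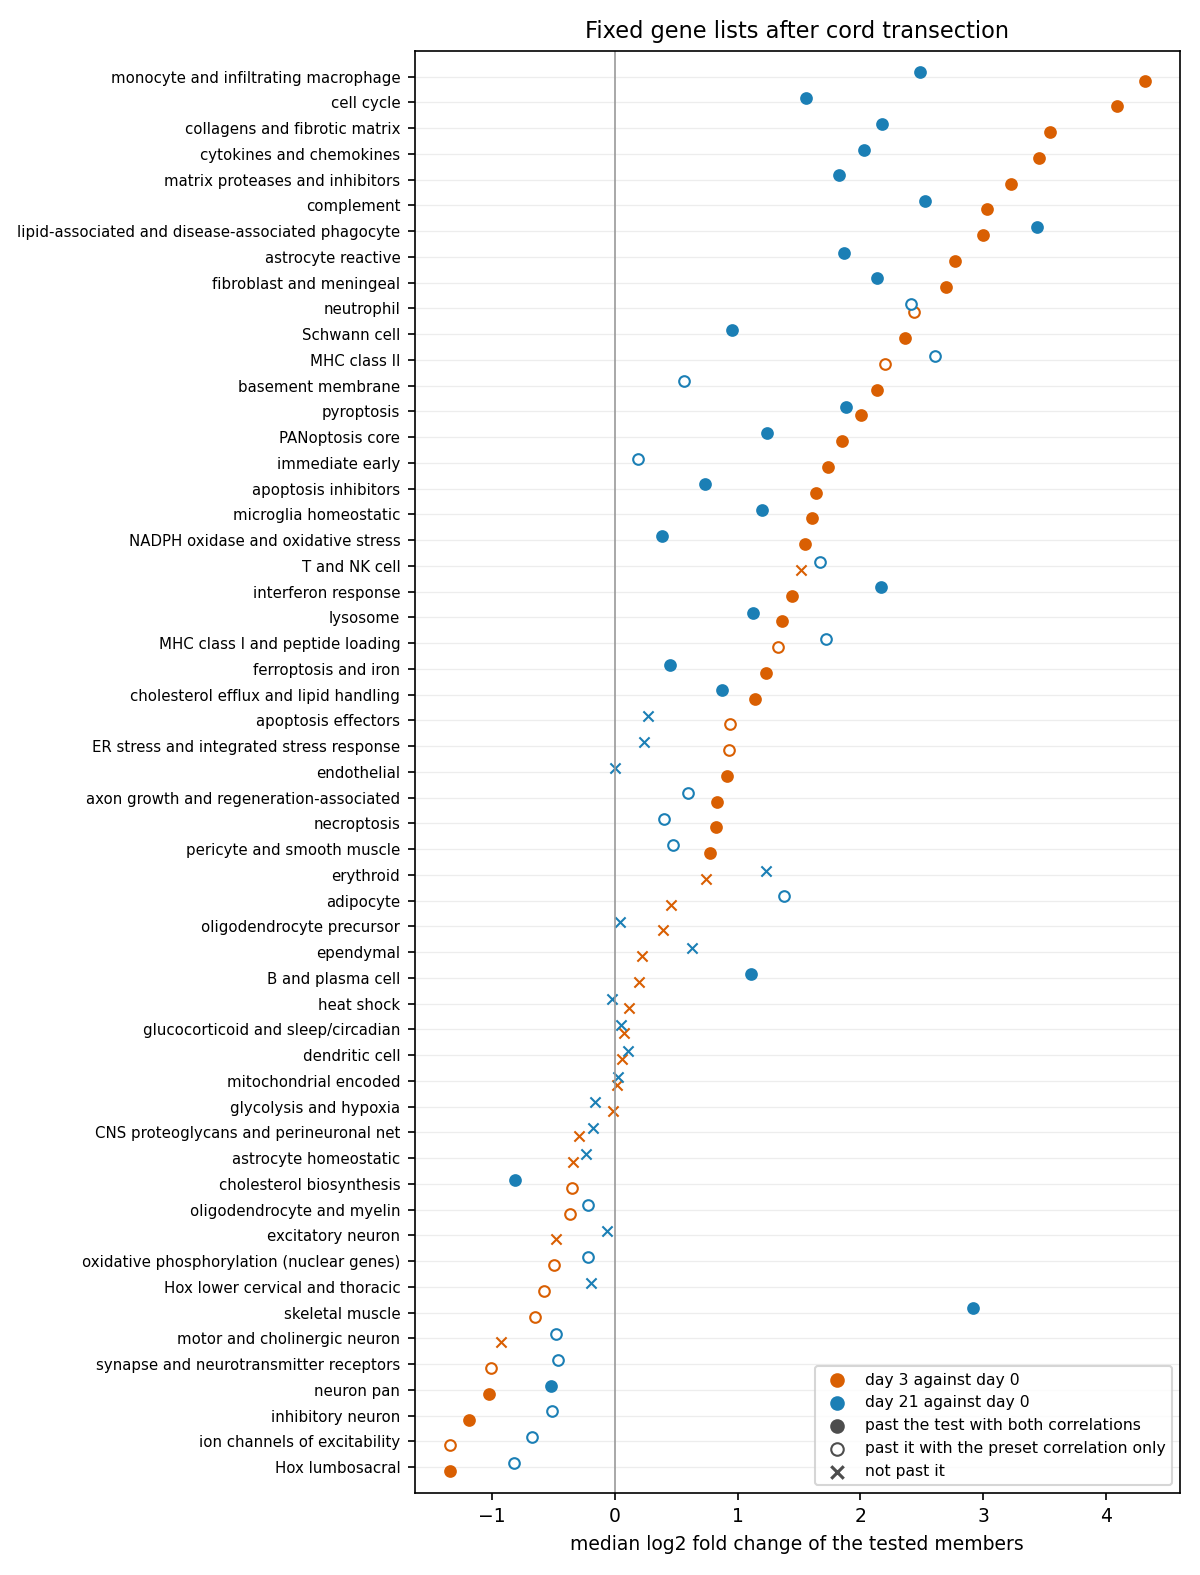
Median log2 fold change of tested members (x axis) for each of the 55 tested lists (1 per line), day 3 against day 0 in orange and day 21 against day 0 in blue. Filled points passed camera with the preset and the estimated correlation, open points with the preset one only, and crosses did not pass. The monocyte and macrophage list lies at 4.32 at day 3 and 2.49 at day 21, and the skeletal muscle list at -0.65 and 2.92.

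The comparison of day 21 with day 0 asked which transcripts differed late after transection. Genes of lipid-laden phagocytes, complement, interferon response, fibrotic matrix, reactive astrocytes and skeletal muscle were higher at day 21. Cholesterol biosynthesis and pan-neuronal genes were lower. Of 29 phagocyte genes 28 rose (median log2 fold change 3.44, camera adjusted p 6.51e-70), and of 22 cholesterol biosynthesis genes 18 fell, or 20 adjusted over the list alone (median -0.82, camera adjusted p 3.77e-12).

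The phagocyte genes were led by the elastase Mmp12, at least 284-fold higher from 0 counts at day 0, and the cysteine protease inhibitor Cst7, which rose from 0.214 ± 0.0424 to 43.4 ± 13.6 FPKM (log2 fold change 7.5 ± 0.32, edgeR adjusted p 9.11e-07). Monocyte and macrophage genes remained higher than at day 0 (23 of 25 higher and 1 lower, median 2.49, camera adjusted p 7.46e-20). Foremost were the NADPH oxidase subunit Cybb and lysozyme Lyz2 (log2 fold changes 4.78 ± 0.24 and 4.60 ± 0.19, edgeR adjusted p 2.36e-06 and 8.88e-07). Complement genes were higher (18 of 21 higher, or 19 adjusted over the list alone, median 2.53, camera adjusted p 1.20e-32). They included the C3a receptor C3ar1 and C1qa, a chain of the initiating C1 complex (log2 fold changes 3.84 ± 0.15 and 3.21 ± 0.31, edgeR adjusted p 8.28e-07 and 0.000102). Interferon response genes rose (28 of 29 higher, or 29 adjusted over the list alone, median 2.17, camera adjusted p 8.33e-32). Ahead were Zbp1, a sensor of Z-form nucleic acids, and the GTPase Gbp7 (log2 fold changes 3.58 ± 0.25 and 3.06 ± 0.68, edgeR adjusted p 1.33e-05 and 0.00945). The Gbp7 call was lost with limma on log2(FPKM + 5) and with quantile normalization (adjusted p over alternatives 5.40e-06 to 0.114). Cytokine and chemokine genes were higher (21 of 31 higher and 1 lower, median 2.03, camera adjusted p 3.05e-15). These included the macrophage chemokine Ccl3 and the interferon-induced Cxcl10 (log2 fold changes 5.59 ± 0.24 and 5.02 ± 0.23, edgeR adjusted p 9.11e-07 and 1.56e-06). MHC class II genes were higher at the preset correlation (11 of 11 higher, median 2.61, camera adjusted p 2.17e-11, adjusted p 0.0561 with an estimated correlation). MHC class I genes were higher at the preset correlation (14 of 17 higher, or 15 adjusted over the list alone, median 1.72, camera adjusted p 1.75e-11, adjusted p 0.104 with an estimated correlation). Both stood higher in day 21 replicate 2 than in the other day 21 libraries (median 0.75 and 0.56). Lysosomal genes were higher (19 of 28 higher and 1 lower, or 21 and 1 adjusted over the list alone, median 1.13, camera adjusted p 4.78e-19). Microglial genes were higher (14 of 20 higher, or 15 adjusted over the list alone, median 1.20, camera adjusted p 1.33e-11). Cholesterol efflux genes were higher (10 of 18 higher, or 11 adjusted over the list alone, median 0.88, camera adjusted p 7.38e-09).

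B and plasma cell genes were higher (4 of 8 higher, median 1.11, camera adjusted p 0.00297). Foremost were the B cell receptor regulator Cd22 and the immunoglobulin kappa constant segment Igkc (log2 fold changes 6.17 ± 0.24 and 2.77 ± 0.40, edgeR adjusted p 8.28e-07 and 0.00114). That list lost its call without day 21 replicate 2 (camera adjusted p 0.0656). T and NK cell genes passed the preset correlation only (3 of 8 higher, or 6 adjusted over the list alone, median 1.67, camera adjusted p 0.024, adjusted p 0.166 with an estimated correlation). Neutrophil genes passed the preset correlation only (15 of 18 higher and 1 lower, median 2.41, camera adjusted p 1.33e-07, adjusted p 0.0737 with an estimated correlation). With genes at 0 set to their bound, the medians of these lists were 1.01 and 2.32, and no other list median moved. Without 1 library the set of tested T and NK cell genes changed, and their median was 2.56 without day 21 replicate 3 and 3.13 to 3.59 without any day 0 or day 3 library. Of them 5 were higher without day 21 replicate 2. The neutrophil genes stood 0.65 higher in day 21 replicate 2 than in the other day 21 libraries.

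Collagen and fibrotic matrix genes stayed above day 0 (27 of 28 higher, or 28 adjusted over the list alone, median 2.17, camera adjusted p 6.22e-65). Ahead were periostin, Postn, and the fibrillar collagen Col3a1 (log2 fold changes 4.89 ± 0.18 and 3.66 ± 0.10, edgeR adjusted p 8.28e-07 and 2.01e-07). Fibroblast and meningeal genes were higher (14 of 20 higher, or 16 adjusted over the list alone, median 2.13, camera adjusted p 4.33e-29). Foremost was the organic cation exporter Slc47a1 (log2 fold change 5.14 ± 0.18, edgeR adjusted p 7.39e-07). Reactive astrocyte genes were higher (26 of 32 higher, median 1.87, camera adjusted p 4.91e-34). Their members included Timp1 and Cxcl10 (log2 fold changes 5.52 ± 0.44 and 5.02 ± 0.23, edgeR adjusted p 3.10e-05 and 1.56e-06). Matrix protease genes were higher (15 of 21 higher and 2 lower, median 1.82, camera adjusted p 2.40e-14). Schwann cell genes were higher (13 of 16 higher, median 0.96, camera adjusted p 4.27e-07), and of the 20 sensory neuron genes 9 were higher and 1 lower by edgeR. Cell cycle genes were higher (24 of 30 higher and 1 lower, or 25 and 1 adjusted over the list alone, median 1.56, camera adjusted p 1.75e-11). Pericyte genes were higher at the preset correlation (9 of 16 higher, median 0.47, camera adjusted p 0.00712, adjusted p 0.0506 with an estimated correlation). Basement membrane genes were higher at the preset correlation (9 of 14 higher, median 0.56, camera adjusted p 0.00148, adjusted p 0.256 with an estimated correlation). Axon growth genes were higher at the preset correlation (12 of 21 higher and 1 lower, or 13 and 1 adjusted over the list alone, median 0.60, camera adjusted p 3.51e-05, adjusted p 0.085 with an estimated correlation). Immediate early genes were higher at the preset correlation (8 of 20 higher and 1 lower, median 0.19, camera adjusted p 0.0081, adjusted p 0.174 with an estimated correlation). NADPH oxidase genes were higher (9 of 21 higher and 1 lower, median 0.38, camera adjusted p 4.00e-05). Ferroptosis and iron genes were higher (10 of 20 higher and 3 lower, or 11 and 4 adjusted over the list alone, median 0.45, camera adjusted p 0.00098). The NADPH oxidase median was 0.16 without day 21 replicate 2, and the immediate early median 0.11 without day 21 replicate 1.

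Skeletal muscle genes rose at day 21 (15 of 16 higher and 1 lower, median 2.92, camera adjusted p 4.84e-21). Foremost were the fast myosin heavy chains Myh1 and Myh2 (log2 fold changes 5.82 ± 0.31 and 5.65 ± 0.30, edgeR adjusted p 3.35e-06 and 3.31e-06). Their summed FPKM was 74.3 ± 4.99 (SD) at day 0, 50.9 ± 0.976 at day 3 and 255 ± 85.6 at day 21, where the libraries held 213, 353 and 198. The 353 belonged to replicate 2, and without it the list's median was 2.47. Of the 16 genes, 10 had a mean of at least 1 FPKM at day 0.

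**Figure D3:**
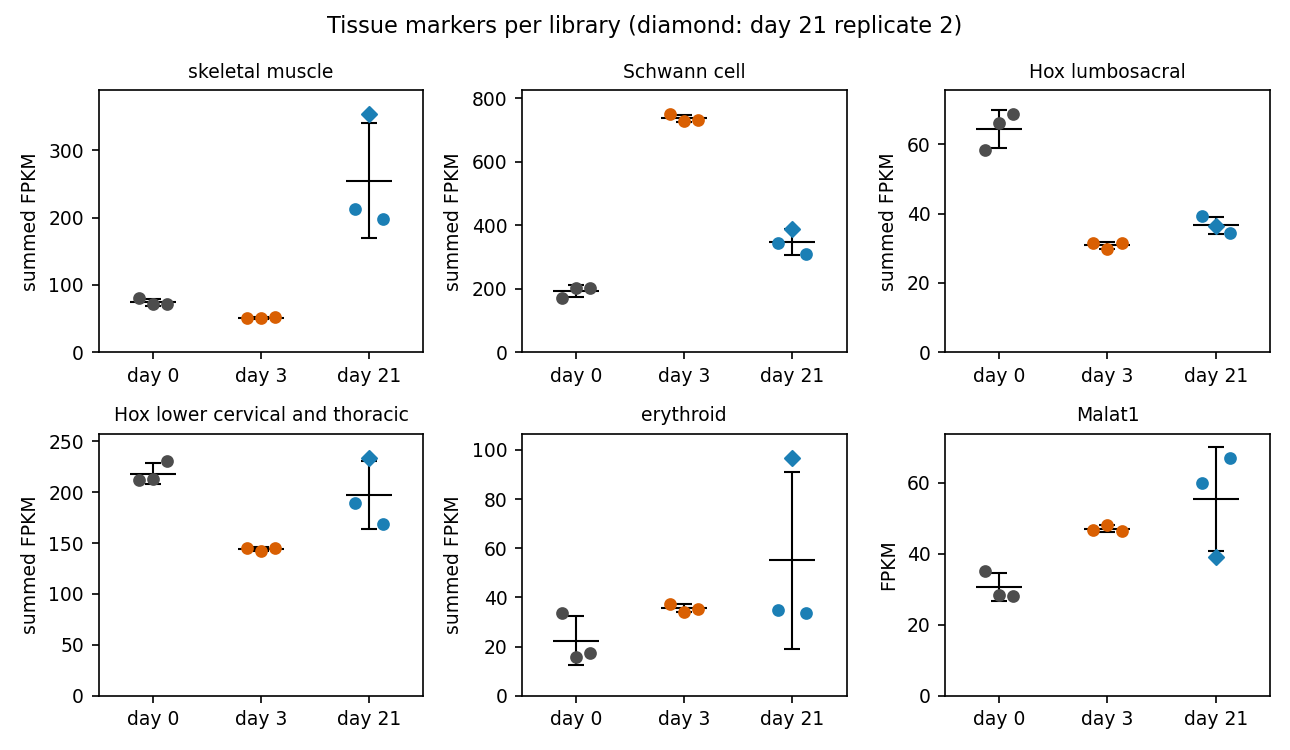
FPKM (y axes, summed over each list) of skeletal muscle, Schwann cell, lumbosacral Hox, lower cervical and thoracic Hox and erythroid genes and of Malat1 at day 0, 3 and 21 (x axes). Points are libraries (3 per day), lines means, bars SD and the diamond day 21 replicate 2. The muscle sum is 198 to 353 at day 21 against a mean of 74.3 at day 0, and the Schwann cell sum has its highest mean, 737, at day 3.

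Pan-neuronal genes fell (13 of 20 lower, or 14 adjusted over the list alone, median -0.52, camera adjusted p 5.92e-06). These included the kinesin Kif5a (log2 fold change -0.84 ± 0.17, edgeR adjusted p 0.00585). The Kif5a call was lost with quantile normalization (adjusted p over alternatives 1.57e-06 to 0.109). Synapse genes were lower at the preset correlation (14 of 28 lower and 1 higher, or 16 and 1 adjusted over the list alone, median -0.46, camera adjusted p 4.25e-05, adjusted p 0.267 with an estimated correlation). Ion channel genes were lower at the preset correlation (6 of 19 lower and 1 higher, or 7 and 1 adjusted over the list alone, median -0.67, camera adjusted p 0.000127, adjusted p 0.239 with an estimated correlation). Inhibitory neuron genes were lower at the preset correlation (5 of 12 lower and 1 higher, or 7 and 1 adjusted over the list alone, median -0.51, camera adjusted p 0.00271, adjusted p 0.0936 with an estimated correlation). Motor neuron genes were lower at the preset correlation (5 of 14 lower and 1 higher, or 5 and 2 adjusted over the list alone, median -0.47, camera adjusted p 0.0197, adjusted p 0.0737 with an estimated correlation). At day 3 they did not pass it (8 of 14 lower and 2 higher, or 8 and 3 adjusted over the list alone, median -0.92, camera adjusted p 0.0545), but were called lower without any 1 day 0 library or day 21 replicate 2 or 3 (camera adjusted p 0.0203 to 0.0387), without the count filter and with limma on log2 FPKM with 0.1 or 1 added (adjusted p over alternatives 0.00795 to 0.121). In day 21 replicate 2 the synapse and ion channel genes stood at -0.41 and -0.73 against the other day 21 libraries. Glra1 remained below day 0 (log2 fold change -1.25 ± 0.27, edgeR adjusted p 0.00756). The GABA receptor subunit Gabra2 rose (log2 fold change 1.1 ± 0.14, edgeR adjusted p 0.000574). Oligodendrocyte and myelin genes were lower at the preset correlation (6 of 26 lower and 2 higher, or 7 and 2 adjusted over the list alone, median -0.22, camera adjusted p 0.0219, adjusted p 0.0872 with an estimated correlation). Lumbosacral Hox genes were lower at the preset correlation (4 of 6 lower, median -0.82, camera adjusted p 0.00629, adjusted p 0.0561 with an estimated correlation). The Hox list also lost its call without day 21 replicate 2 (camera adjusted p 0.0919) and without the count filter (adjusted p 0.101). Nuclear oxidative phosphorylation genes were lower at the preset correlation (5 of 36 lower, median -0.22, camera adjusted p 0.00755, adjusted p 0.627 with an estimated correlation). That call was lost without day 0 replicate 1, day 21 replicate 1 or day 21 replicate 3 (camera adjusted p 0.0562, 0.0552 and 0.104), with medians of 0.017, -0.073 and 0.0087. These genes stood 1.07 higher in day 21 replicate 2 than in the other day 21 libraries. Their median was -0.62 without it, with 30 genes lower, and -0.36 and -0.35 without day 0 replicate 2 or 3. Leaving out day 21 replicate 2 also gave 13 oligodendrocyte, 13 ion channel and 8 motor neuron genes as lower.

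At day 21 that rule took as highest the apolipoprotein Apoc4 (at least 65.2-fold, 0 counts at day 0; its place is not set by a measured fold), Sprr1a (chromosome 3, 92483952 to 92485895, GRCm38), Cst7 (chromosome 2, 150570415 to 150578944), the inhibitory receptor Lilrb4a, Tgm1 and the beta-glucan receptor Clec7a. The log2 fold changes of the last 5 were 7.92 ± 0.36, 7.5 ± 0.32, 7.41 ± 0.35, 7.21 ± 0.30 and 6.53 ± 0.32, with edgeR adjusted p of at most 2.07e-06. Lilrb4a is uncertain, since a second entry overlaps 92.8% of its exon bases. The 6 lowest were Lrrc4b, a synaptic adhesion protein, Srgap3, Bcl2l2, an inhibitor of apoptosis, Pogk, Add2 and Rhof. Their log2 fold changes were -2.0 ± 0.60, -1.98 ± 0.47, -1.66 ± 0.52, -1.56 ± 0.32, -1.48 ± 0.45 and -1.45 ± 0.37, with edgeR adjusted p of 0.00605 to 0.039. The Lrrc4b call was lost without day 0 replicate 1 or 2 or any day 21 library (adjusted p 0.0714 to 0.131). Bcl2l2 was called only with all libraries or without day 21 replicate 3 (adjusted p otherwise 0.0603 to 0.139), where its log2 fold change was -2.71. Add2 lost its call without any day 0 library or day 21 replicate 1 or 2 (adjusted p 0.0525 to 0.0938), and Rhof without day 0 replicate 2 or day 21 replicate 2 or 3 (adjusted p 0.0564 to 0.0683). A filter at 5 FPKM ended the Lrrc4b, Bcl2l2 and Add2 calls, a fit of only 2 groups the Bcl2l2 and Add2 calls, and sample weights the Lrrc4b and Rhof calls. Limma on log2 FPKM and quantile normalization also ended the Lrrc4b call. Over alternatives the adjusted p was 0.00163 to 0.203 for Lrrc4b, 0.00362 to 0.101 for Bcl2l2, 0.00391 to 0.0801 for Add2 and 0.000848 to 0.0815 for Rhof.

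At day 21 camera called 31 of 55 lists higher and 9 lower, and 21 and 2 with an estimated correlation. Median, mean and test differed in sign for heat shock (median -0.023, mean 0.081, camera adjusted p 0.55, lower), endothelial (median 0.0029, mean 0.043, camera adjusted p 0.77, lower), mitochondrial encoded (median 0.026, mean 0.21, camera adjusted p 0.834, lower), glucocorticoid and sleep/circadian (median 0.049, mean 0.14, camera adjusted p 0.894, lower) and dendritic cell (median 0.11, mean 0.21, camera adjusted p 0.79, lower). Of single genes, 2949 were higher and 1864 lower by edgeR. Lower genes numbered 1072 and 1011 without day 0 replicate 2 or 3 and 3748 without day 21 replicate 2. Limma on log2(FPKM + 1) gave 2616 higher and 1137 lower genes, and 1762 and 1844 with quantile normalization (median shift -0.12, TPM -0.13).

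The series title names PANoptosis, a form of inflammatory cell death that joins pyroptosis, apoptosis and necroptosis. At day 3 most of its core genes were higher than at day 0 (18 of 21 higher and 1 lower, median 1.85, camera adjusted p 2.47e-09). The largest rises were those of the cytokine Il1b, the necroptosis kinase Ripk3, Zbp1 and the necroptosis effector Mlkl (log2 fold changes 4.60 ± 0.57, 4.4 ± 0.47, 4.19 ± 0.25 and 3.15 ± 0.37, edgeR adjusted p 0.000183, 6.92e-05, 1.67e-06 and 0.000139). Ripk3 rose from 0.107 ± 0.0480 to 2.45 ± 0.483 FPKM and Zbp1 from 0.0772 ± 0.0248 to 1.47 ± 0.0669. The initiator caspase Casp8, the inflammasome adaptor Pycard, the inflammasome sensor Nlrp3, the receptor Tnfrsf1a and the pore-forming gasdermin Gsdmd rose too (log2 fold changes 2.86 ± 0.21, 2.70 ± 0.19, 2.59 ± 0.22, 2.33 ± 0.10 and 2.29 ± 0.15, edgeR adjusted p 7.12e-06, 4.95e-06, 1.73e-05, 3.50e-07 and 3.28e-06). Casp6, Ripk1, Casp1, Irf1, Aim2, Bak1 and Fadd rose by 1.88, 1.85, 1.77, 1.72, 1.35, 1.29 and 0.82 log2 units (edgeR adjusted p of at most 0.0023). The Aim2 call was lost with quantile normalization (adjusted p over alternatives 1.79e-07 to 0.0861). Gsdme, another gasdermin, fell (log2 fold change -0.92 ± 0.17, edgeR adjusted p 0.00219). Bax and Il18 were not called (log2 fold changes 0.71 ± 0.32 and -0.11 ± 0.25, edgeR adjusted p 0.103 and 0.76). Bax was called without day 21 replicate 2 (adjusted p 0.0169), in a fit of only 2 groups and with 3 other settings (adjusted p over alternatives 0.000824 to 0.171). Mefv was too low to be tested, with 29 counts at day 3 and 0 on the other days.

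At day 21 fewer core genes were above day 0 (13 of 21 higher and 1 lower, or 15 and 1 adjusted over the list alone, median 1.24, camera adjusted p 3.17e-07). Zbp1, Il1b, Pycard, the DNA sensor Aim2 and Casp1, the inflammatory caspase, were the highest (log2 fold changes 3.58 ± 0.25, 3.22 ± 0.64, 2.12 ± 0.19, 2.07 ± 0.21 and 1.95 ± 0.30, edgeR adjusted p 1.33e-05, 0.00536, 6.06e-05, 0.000131 and 0.00159). Gsdmd, Casp8, Irf1, Nlrp3, Tnfrsf1a and Casp6 were also higher (log2 fold changes 1.82 ± 0.15, 1.76 ± 0.21, 1.55 ± 0.23, 1.46 ± 0.23, 0.97 ± 0.10 and 0.71 ± 0.14, edgeR adjusted p 4.09e-05, 0.00036, 0.00135, 0.00161, 0.000134 and 0.00636). With quantile normalization, with its median shift of -0.12, Nlrp3 was not called and the sign of Casp6 turned (-0.070, adjusted p 0.534). Their adjusted p over alternatives was 8.92e-06 to 0.97 and 0.00284 to 0.534. Ripk3 was higher and Gsdme lower (log2 fold changes 1.70 ± 0.54 and -0.55 ± 0.17, edgeR adjusted p 0.0433 and 0.0377). Ripk3 lost its call without any library but day 21 replicates 1 and 3 (adjusted p 0.0582 to 0.124), and its log2 fold change was 1.01 without day 21 replicate 2. The Gsdme call was lost without any library but day 21 replicate 2 (adjusted p 0.05004 to 0.161). With quantile normalization Ripk3 had a log2 fold change of -0.014 (adjusted p 0.964). Ripk3 was not called either with limma on log2(FPKM + 1) or log2(FPKM + 5), TPM, sample weights or no count filter. Gsdme was not called with the length trend removed or in a fit of only 2 groups. Over alternatives the adjusted p was 0.013 to 0.964 for Ripk3 and 0.000469 to 0.295 for Gsdme. Mlkl, Ripk1, Fadd, Bax, Bak1 and Il18 were not called, with edgeR adjusted p of 0.0507 to 0.332. Leaving out day 21 replicate 2 gave calls for Mlkl and Ripk1 (adjusted p 0.0476 and 0.00864), and leaving out day 0 replicate 3 gave one for Mlkl (adjusted p 0.0276). DESeq2 and 5 other settings called Mlkl, and sample weights called Ripk1 and Il18, the last also with the length trend removed. Over alternatives the adjusted p was 0.0211 to 0.433 for Mlkl, 0.0311 to 0.988 for Ripk1 and 0.0193 to 0.179 for Il18.

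Between day 3 and day 21 the core genes fell (15 of 21 lower and 1 higher, or 15 and 2 adjusted over the list alone, median -0.77, camera adjusted p 0.000203). Ripk3, Mlkl, Il1b, Tnfrsf1a and Ripk1 fell the most (log2 fold changes -2.70 ± 0.40, -1.91 ± 0.34, -1.38 ± 0.41, -1.36 ± 0.10 and -1.32 ± 0.34, edgeR adjusted p 0.00143, 0.0035, 0.0351, 2.82e-05 and 0.0201). Casp6, Nlrp3, Casp8, Bak1, Zbp1, Pycard, Fadd and Gsdmd fell by 1.18, 1.13, 1.1, 1.09, 0.61, 0.58, 0.54 and 0.48 log2 units (edgeR adjusted p of at most 0.0398). Aim2 rose (log2 fold change 0.72 ± 0.20, edgeR adjusted p 0.024). Casp1, Irf1, Bax, Gsdme and Il18 were not called (edgeR adjusted p 0.0631 to 0.724). Il18 was called without day 21 replicate 3 (adjusted p 0.0459) and with 6 other settings, DESeq2 among them (adjusted p over alternatives 0.00541 to 0.11), and Bax with sample weights (adjusted p over alternatives 0.0189 to 0.838). Calls were lost without 1 library for Gsdmd (any but day 21 replicate 2, adjusted p 0.0501 to 0.115) and for Zbp1 and Pycard (day 0 replicate 2, day 21 replicate 1 or 3, or any day 3 library, adjusted p 0.0589 to 0.122 and 0.0551 to 0.123). The same held for Il1b (day 0 replicate 1 or 3, day 21 replicate 3 or any day 3 library, adjusted p 0.0516 to 0.102) and Fadd (day 21 replicate 1 or 3, or day 3 replicate 2 or 3, adjusted p 0.0549 to 0.087). It also held for Aim2 (day 21 replicate 3, or day 3 replicate 1 or 3, adjusted p 0.0688 to 0.0955) and Ripk1 (day 21 replicate 1 or day 3 replicate 1, adjusted p 0.0622 and 0.0725). In a fit of only the 2 groups Gsdmd, Zbp1, Pycard and Ripk1 were not called. The first 3 also lost their calls without the count filter and with limma on log2(FPKM + 0.1), and Gsdmd with quantile normalization and a filter at 5 FPKM. Over alternatives the adjusted p of the 4 genes was 0.000479 to 0.0997, 0.00423 to 0.0876, 0.000371 to 0.07 and 0.000535 to 0.0603.

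Pyroptosis genes were higher at day 3 (17 of 20 higher and 1 lower, median 2.0, camera adjusted p 7.63e-07). They were also higher at day 21 (13 of 20 higher and 1 lower, or 15 and 1 adjusted over the list alone, median 1.89, camera adjusted p 8.10e-10). The flagellin sensor Naip5 led at both days (log2 fold changes 3.12 ± 0.34 and 3.37 ± 0.34, edgeR adjusted p 7.40e-05 and 0.000122). Necroptosis genes were higher at day 3 (15 of 25 higher and 1 lower, median 0.82, camera adjusted p 0.000641). At day 21 they were higher with the preset correlation only (9 of 25 higher and 1 lower, or 10 and 1 adjusted over the list alone, median 0.40, camera adjusted p 0.0165, adjusted p 0.0603 with an estimated correlation). Apoptosis effector genes passed the preset correlation at day 3 (14 of 25 higher and 1 lower, or 14 and 2 adjusted over the list alone, median 0.94, camera adjusted p 0.016, adjusted p 0.0609 with an estimated correlation). They did not pass the test at day 21 (7 of 25 higher and 1 lower, median 0.27, camera adjusted p 0.297). Apoptosis inhibitors were higher at day 3 (10 of 14 higher, median 1.64, camera adjusted p 2.69e-05). At day 21 they were higher as well (9 of 14 higher and 1 lower, or 10 and 1 adjusted over the list alone, median 0.73, camera adjusted p 0.000737). Ahead were Bcl2a1b and Bcl2a1d (log2 fold changes 4.43 ± 0.41 and 4.02 ± 0.58, edgeR adjusted p 2.75e-05 and 0.000478 at day 3). These near-identical copies share reads, and 49.1% of Bcl2a1b exon bases overlap another gene, so their values are uncertain.

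Locations on GRCm38 were chromosome 2, 173206612 to 173218923 for Zbp1 (ENSMUSG00000027514), chromosome 14, 55784996 to 55788857 for Ripk3 (ENSMUSG00000022221), chromosome 8, 111311797 to 111338177 for Mlkl, chromosome 1, 58795374 to 58847503 for Casp8, chromosome 15, 75862339 to 75867404 for Gsdmd and chromosome 11, 59541568 to 59566956 for Nlrp3. Counts were summed over whole genes, so exons and untranslated regions were not separated. Exons of Pycard, Bax and Bak1 overlap other genes over 12.8%, 12.2% and up to 18.2% of their bases, and strand use in counting is not given in the sources used here.

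**Figure D4:**
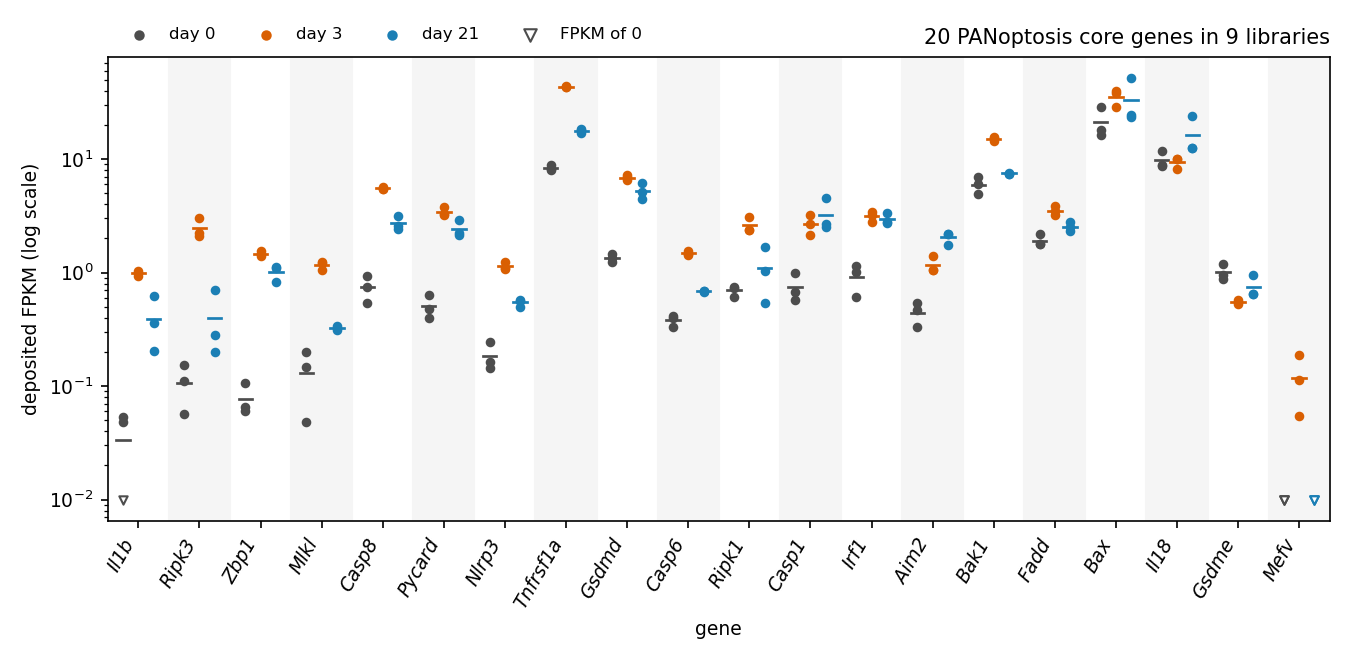
FPKM (y axis, log scale) of 20 PANoptosis core genes (x axis) at day 0 (grey), 3 (orange) and 21 (blue). Points are libraries (3 per day), short lines are means and open triangles at the foot mark an FPKM of 0. Mean FPKM of Ripk3 on days 0, 3 and 21 is 0.107, 2.45 and 0.396, and of Aim2 0.444, 1.18 and 2.04.

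The comparison of day 21 with day 3 asked how the early response had changed by the later day. Cell cycle, monocyte, basement membrane, collagen, immediate early and Schwann cell genes were lower at day 21. Skeletal muscle, interferon response, B and plasma cell and pan-neuronal genes were higher. Of 30 cell cycle genes 29 fell (median log2 fold change -2.39, camera adjusted p 4.82e-48), and 14 of 16 muscle genes rose (median 3.86, camera adjusted p 8.10e-40).

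The mitotic kinesin Kif20a and the cyclin Ccnb2 fell the most among cell cycle genes (log2 fold changes -3.18 ± 0.22 and -3.15 ± 0.18, edgeR adjusted p 2.45e-05 and 8.20e-06), and 29.3% of Kif20a exon bases overlap another gene. Monocyte and macrophage genes fell (19 of 25 lower, or 20 and 1 higher adjusted over the list alone, median -1.56, camera adjusted p 2.37e-22). Arg1 went from 66.1 ± 2.5 to 0.358 ± 0.311 FPKM and Saa3 from 49.8 ± 3.69 to 0.636 ± 0.471. Basement membrane genes fell (13 of 14 lower, median -1.67, camera adjusted p 3.99e-21). The chains Col4a1 and Col4a2 were among them (log2 fold changes -2.92 ± 0.13 and -2.5 ± 0.09, edgeR adjusted p 2.64e-06 and 1.12e-06). Collagen and fibrotic matrix genes fell too (23 of 28 lower and 1 higher, or 24 and 2 adjusted over the list alone, median -1.32, camera adjusted p 2.77e-26). Lox and Tnc were among them (log2 fold changes -3.20 ± 0.18 and -3.0 ± 0.10, edgeR adjusted p 7.41e-06 and 1.12e-06). Immediate early genes were lower (16 of 20 lower and 1 higher, median -1.35, camera adjusted p 1.04e-17). Ahead were the AP-1 members Fosl1 and Fosl2 (log2 fold changes -3.83 ± 0.22 and -2.75 ± 0.28, edgeR adjusted p 8.38e-06 and 0.000163), with 57.2% of Fosl1 exon bases overlapping another gene. Schwann cell genes fell (15 of 16 lower, median -1.04, camera adjusted p 3.70e-20), Fbln2 and Ngfr foremost (log2 fold changes -3.93 ± 0.16 and -3.64 ± 0.16, edgeR adjusted p 2.04e-06 and 2.22e-06). Endothelial genes were lower (16 of 22 lower and 1 higher, median -0.90, camera adjusted p 1.71e-09). These included Cdh5 and the adhesion molecule Pecam1 (log2 fold changes -2.49 ± 0.18 and -1.66 ± 0.16, edgeR adjusted p 3.52e-05 and 0.000151). Ferroptosis and iron genes were lower (10 of 20 lower, or 12 adjusted over the list alone, median -0.64, camera adjusted p 2.44e-09). Hmox1 was at 10.8 ± 1.56 FPKM at day 21 (log2 fold change -4.47 ± 0.14, edgeR adjusted p 1.02e-06). Of these genes 16 were lower without day 21 replicate 2.

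Reactive astrocyte genes were lower at day 21 (24 of 32 lower and 2 higher, or 25 and 3 adjusted over the list alone, median -1.14, camera adjusted p 2.30e-12). Matrix protease genes were lower (14 of 21 lower and 3 higher, or 15 and 3 adjusted over the list alone, median -1.17, camera adjusted p 8.68e-12). Fibroblast genes were lower (14 of 20 lower and 2 higher, or 14 and 3 adjusted over the list alone, median -0.92, camera adjusted p 1.04e-06). Pericyte genes were lower (9 of 16 lower and 1 higher, or 9 and 2 adjusted over the list alone, median -0.74, camera adjusted p 0.000289). Cytokine genes were lower (15 of 31 lower and 5 higher, median -0.63, camera adjusted p 3.31e-07). Csf3 had a day 21 to day 3 ratio of 0.00361 (counting interval 9.12e-05 to 0.0203). Necroptosis genes were lower (12 of 25 lower, or 12 and 1 higher adjusted over the list alone, median -0.42, camera adjusted p 0.00718). Apoptosis inhibitor genes were lower (7 of 14 lower, median -0.71, camera adjusted p 0.00535). NADPH oxidase genes were lower (9 of 21 lower and 1 higher, or 9 and 2 adjusted over the list alone, median -0.44, camera adjusted p 0.000289). Cholesterol efflux genes were lower (7 of 18 lower and 2 higher, or 11 and 3 adjusted over the list alone, median -0.38, camera adjusted p 0.000413). Apoptosis effector genes were lower at the preset correlation (9 of 25 lower, or 10 adjusted over the list alone, median -0.46, camera adjusted p 0.0141, adjusted p 0.0688 with an estimated correlation). Complement genes were lower at the preset correlation (12 of 21 lower and 2 higher, or 13 and 2 adjusted over the list alone, median -0.55, camera adjusted p 0.00602, adjusted p 0.0663 with an estimated correlation). Lysosomal genes were lower at the preset correlation (13 of 28 lower and 1 higher, or 16 and 2 adjusted over the list alone, median -0.42, camera adjusted p 0.00123, adjusted p 0.177 with an estimated correlation). Axon growth genes were lower at the preset correlation (12 of 21 lower and 4 higher, or 13 and 4 adjusted over the list alone, median -0.59, camera adjusted p 9.90e-05, adjusted p 0.0824 with an estimated correlation). Cholesterol biosynthesis genes were lower at the preset correlation (8 of 22 lower, or 9 adjusted over the list alone, median -0.46, camera adjusted p 0.00887, adjusted p 0.105 with an estimated correlation). Glycolysis genes were lower at the preset correlation (5 of 22 lower, median -0.19, camera adjusted p 0.0114, adjusted p 0.0575 with an estimated correlation). ER stress genes were lower at the preset correlation (8 of 18 lower, or 10 adjusted over the list alone, median -0.62, camera adjusted p 0.00355, adjusted p 0.339 with an estimated correlation). Heat shock genes were lower at the preset correlation (6 of 13 lower and 3 higher, or 7 and 3 adjusted over the list alone, median -0.54, camera adjusted p 0.0356, adjusted p 0.339 with an estimated correlation). Without day 21 replicate 1 the apoptosis effector call was lost (camera adjusted p 0.0535), and the heat shock call was lost without day 0 replicate 1, day 21 replicate 1 or day 21 replicate 3 (camera adjusted p 0.0536, 0.0709 and 0.0823) and with limma on log2 FPKM with 0.1 or 1 added (adjusted p over alternatives 0.00804 to 0.339). Medians moved without 1 library for NADPH oxidase genes (-0.29, -0.79 and -0.26 without day 21 replicates 1, 2 and 3), ER stress genes (-0.98 without day 21 replicate 2) and glycolysis genes (-0.11 without day 21 replicate 3). The counts of lower genes without day 21 replicate 2 were 23 for lysosome, 15 for ER stress, 15 for NADPH oxidase, 14 for cholesterol biosynthesis, 13 for cholesterol efflux and 12 for glycolysis.

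Interferon response genes rose further between day 3 and day 21 (13 of 29 higher and 4 lower, or 13 and 5 adjusted over the list alone, median 0.51, camera adjusted p 0.00129). Ahead were the antiviral proteins Ifit3 and Ifit1 (log2 fold changes 1.33 ± 0.17 and 1.27 ± 0.14, edgeR adjusted p 0.00069 and 0.000281). B and plasma cell genes rose (5 of 8 higher, median 1.0, camera adjusted p 0.00215). Foremost were Igkc and the heavy chain Ighm (log2 fold changes 1.87 ± 0.38 and 1.13 ± 0.11, edgeR adjusted p 0.00658 and 0.000166). Pan-neuronal genes were higher at day 21 than at day 3 (10 of 20 higher, or 14 adjusted over the list alone, median 0.50, camera adjusted p 8.82e-06). These included Map2 and the RNA-binding protein Elavl4 (log2 fold changes 1.41 ± 0.41 and 1.01 ± 0.11, edgeR adjusted p 0.0328 and 0.000239). The Map2 call was lost without day 0 replicate 2, day 21 replicate 1 or 3 or any day 3 library (adjusted p 0.0504 to 0.107), with limma on log2(FPKM + 5), with TPM and in a fit of only 2 groups (adjusted p over alternatives 0.00288 to 0.0646). Its log2 fold change was 0.82 without day 21 replicate 3. Synapse genes were higher at the preset correlation (14 of 28 higher, or 17 adjusted over the list alone, median 0.58, camera adjusted p 3.31e-06, adjusted p 0.269 with an estimated correlation). Ion channel genes were higher at the preset correlation (10 of 19 higher, or 11 adjusted over the list alone, median 0.68, camera adjusted p 7.26e-05, adjusted p 0.269 with an estimated correlation). Inhibitory neuron genes were higher at the preset correlation (6 of 12 higher, or 8 adjusted over the list alone, median 0.81, camera adjusted p 0.000555, adjusted p 0.0824 with an estimated correlation). Glra1 rose from 6.59 ± 0.469 to 22.2 ± 7.87 FPKM, below its 48.7 ± 6.80 at day 0 (log2 fold change 1.69 ± 0.27, edgeR adjusted p 0.00218). The counts of higher genes without day 21 replicate 2 were 22 for synapse, 18 for ion channels, 12 for inhibitory neurons and 9 for thoracic Hox genes. Lower cervical and thoracic Hox genes were higher at the preset correlation (4 of 18 higher, or 7 adjusted over the list alone, median 0.35, camera adjusted p 0.0163, adjusted p 0.315 with an estimated correlation), a call also lost without day 21 replicate 2 (camera adjusted p 0.0825).

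At day 21 over day 3 the 5 FPKM rule took 6 muscle genes as highest. They were the creatine kinase Ckm (chromosome 7, 19411094 to 19421583), Myh1, the calcium pump Atp2a1, the troponin Tnnc2, Tcap and Pgam2. Their log2 fold changes were 5.69 ± 0.27, 5.39 ± 0.30, 5.38 ± 0.26, 5.36 ± 0.51, 5.14 ± 0.50 and 4.83 ± 0.62 (edgeR adjusted p 3.13e-06 to 0.00064), and 74.0% of Tnnc2 and 21.9% of Atp2a1 exon bases overlap other genes. The rule's lowest were Arg1, the adhesion receptor Selp, Saa3, Serpina3m, Tmem252 and Il17b. Their log2 fold changes were -7.56 ± 0.53, -6.46 ± 0.43, -6.34 ± 0.41, -6.14 ± 0.31, -4.90 ± 0.15 and -4.87 ± 0.52 (edgeR adjusted p 1.02e-06 to 0.000231).

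Camera called 8 of 55 lists higher and 26 lower at day 21 against day 3, and 4 and 18 with an estimated correlation. Median, mean and test differed in sign for astrocyte homeostatic (median -0.021, mean 0.10, camera adjusted p 0.443, higher), dendritic cell (median -0.0075, mean 0.047, camera adjusted p 0.594, higher), CNS proteoglycans and perineuronal net (median 0.025, mean -0.094, camera adjusted p 0.876, higher), neutrophil (median 0.14, mean -0.53, camera adjusted p 0.125, lower) and T and NK cell (median 0.30, mean -0.20, camera adjusted p 0.842, higher). Of single genes, 1928 were higher and 2657 lower by edgeR. Without day 21 replicate 2, 3941 were higher and 4305 lower. Without day 3 replicate 1, 2 or 3, 1006, 1066 and 1038 were higher. Limma with quantile normalization gave 2272 higher and 2134 lower genes (51.6% higher, against 47.0% without it and 42.1% by edgeR).

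Over the 3 comparisons, 2232 genes were higher than day 0 at both days and 1394 lower at both, while 63 were called in opposite directions. Transient genes, called at day 3 and called the other way from day 3 to day 21, numbered 2225 higher and 1149 lower. Late genes, called at day 21 against both other days and not at day 3, numbered 378 higher and 164 lower. Both comparisons share the day 0 libraries. In 20 simulations of unchanged groups at most 1 gene was higher per day, so 0 at both decides nothing. Independent lists of these sizes would share 731 higher and 364 lower genes. Across genes the fold changes at day 3 and day 21 correlated at 0.788 (simulated 0.486), with a covariance of 0.955 against a simulated 0.0596 and a difference of 0.895. The 3 day 0 libraries were too few to split, so part of the excess may come from the shared controls. Without day 21 replicate 2 the counts were 2663 lower at both, 743 late higher, 585 late lower and 2522 transient lower. Without day 0 replicate 2 or 3 there were 816 and 787 lower at both and 83 and 77 late lower, and without any 1 day 3 library 218 to 248 late higher, 74 to 77 late lower and 610 to 618 transient lower.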

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

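The muscle test of day 21 replicate 2 alone was chosen after its result was seen. So was the length-trend test of the core genes at day 21.

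For 22 of 55 lists the fold changes against day 0 differed between day 3 and day 21, by the test of day 21 against day 3 with both correlations. Medians of that difference were negative for cell cycle (-2.39), basement membrane (-1.67), monocyte and macrophage (-1.56), immediate early (-1.35), collagen (-1.32), matrix protease (-1.17), reactive astrocyte (-1.14), Schwann cell (-1.04), fibroblast (-0.92) and endothelial genes (-0.90). They were also negative for PANoptosis core (-0.77), pericyte (-0.74), apoptosis inhibitor (-0.71), ferroptosis and iron (-0.64), cytokine (-0.63), NADPH oxidase (-0.44), necroptosis (-0.42) and cholesterol efflux genes (-0.38). Medians were positive for pan-neuronal (0.50), interferon response (0.51), B and plasma cell (1.0) and skeletal muscle genes (3.86).

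Muscle genes were higher at day 21, and sensory neuron genes, Scn10a and others, at day 3 and, for 9 of 20 with 1 lower, at day 21. The day 21 replicate 2 library alone was argued against, since the muscle median stayed at 2.47 without it. Muscle in the samples could be a source and stays open: 70.4% of 27 tested genes of a second muscle list were higher, between the 50% and 80% set in advance, while the log2 ratio of the rise between replicates 1 and 3 (SD 0.324 across the 15 of 16 fixed muscle genes that rose in both) decides nothing, as these libraries held like amounts (213 and 198 FPKM). Of the second list's 30 genes, led by Tcap at 13.99 FPKM at day 21 and 0.599 at day 0 and Cox6a2 at 10.6 and 0.673, 6 had at least 1 FPKM at day 0 and 0 are in another list. At day 3, 70.0% of 20 sensory neuron genes were higher (18 tested, 6 at or above 1 FPKM at day 0, 1 in another list). Every tested gene under 1 FPKM at day 0 was higher, such as Avil (0.0563 to 13.9 FPKM). Prph, Calcb, Prrxl1 and Th, not called, had 47.5, 5.50, 2.01 and 1.32 FPKM at day 0. Ganglion tissue and, untested, a change of expression in the cord stay open on both days.

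PANoptosis core genes were higher after injury. A gene-length trend between libraries was argued against, since 99.6% of the core median at day 3 and 97.4% at day 21 remained with the trend removed, and the median log2 fold changes of the shortest and longest 20% of genes were 0.040 and -0.082 at day 3 and 0.12 and -0.064 at day 21. A larger share of leukocytes may account for the median rise. General leukocyte genes (20) had medians of 2.92 and 2.57, with 20 and 18 called higher. At day 3 Il1b, Ripk3, Zbp1 and Mlkl rose above 2.92, but most core genes did not. The median of core minus leukocyte was -1.07 (SE 0.381) at day 3 and -1.33 (SE 0.279) at day 21. Of these leukocyte genes, led by Tyrobp at 16.97, 141 and 202 FPKM on days 0, 3 and 21 and Cd68 at 4.60, 124 and 91.3, 16 had at least 1 FPKM at day 0 and 9 are in a fixed list. Expression within resident cells was not separated from cell number in bulk tissue.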

How the results depend on the processing

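Only the length-trend setting was chosen after seeing the data. Over settings that left out no library, named genes kept direction and side of the threshold in 1675 of 1710 instances for day 3 against day 0, 1650 of 1724 for day 21 against day 0 and 1614 of 1655 for day 21 against day 3, and over left-out libraries in 1094 of 1134, 1060 of 1152 and 1027 of 1098. Lists did so in 358, 346 and 359 of 377 and in 489, 476 and 476 of 495. With quantile normalization Casp6 (-0.070) and Ripk3 (-0.014) at day 21 against day 0 turned sign, and the cause was not tested. It called 1762 genes higher at day 21 than day 0, 1283 higher at both days and 8 core genes higher at day 21, with the share of higher calls at 42.6% at day 3 and 48.9% at day 21 against 56.0% and 61.3%. TPM gave 46.7% and 51.4% and 247 late higher genes. Limma on log2(FPKM + 0.1) gave 71.3% at day 21.

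With at least 5 FPKM required, which tests fewer genes, 1983 genes were higher and 1775 lower at day 3, 1395 and 691 at day 21, and 1243 and 1262 at day 21 against day 3, with 1121 higher and 585 lower at both days, 160 late higher, 42 late lower, 1116 transient higher, and 5 and 3 core genes higher at day 3 and day 21. Sample weights gave 5710 higher and 5215 lower genes at day 3, 4357 and 3946 at day 21, and 4419 and 4832 at day 21 against day 3. They also gave 2937 lower at both, 779 late higher, 569 late lower, 3728 transient higher and 2844 transient lower. Limma on log2 FPKM with 0.1, 1 and 5 added gave 1073, 1137 and 1186 lower at day 21 and 72, 70 and 70 late lower, and with 0.1 and 1 added 862 and 917 lower at both. A fit of only 2 groups called 9966 genes at day 3 against 7307, but gave 801 lower at day 21 (72.5% of calls higher), 722 lower at both, 168 late higher and 26 late lower. The length trend removed gave 287 late lower. Estimated correlations left 3 and 2 lists lower at day 3 and day 21 and 4 higher at day 21 against day 3. Day 21 replicate 2 lowered day 3 calls through the shared fit (10245 without it). Apart from this, fewer genes tested and estimated correlation, the cause was not tested.

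Without 1 library, counts ranged from 2361 to 4891 lower at day 3, 1011 to 3748 lower at day 21, 1006 to 3941 higher and 1887 to 4305 lower at day 21 against day 3, 787 to 2663 lower at both, 218 to 743 late higher, 74 to 585 late lower and 610 to 2522 transient lower. In each the highest was without day 21 replicate 2. DESeq2 called 7792, 5498 and 5248 genes in the 3 comparisons. Replicate numbers did not pair the samples, as deviations of same-numbered libraries correlated at -0.127 to 0.0997. With the replicate block, 6589, 3834 and 3640 genes were called and 81 were late lower. The block ended the calls of Gabrb2 and Hs6st3 at day 3, Add2, Gsdme and Ripk3 at day 21 against day 0, and Gsdmd, Il1b, Pycard and Zbp1 at day 21 against day 3 (adjusted p 0.0504 to 0.0922). It gave calls of homeostatic astrocyte (lower) and erythroid genes (higher) at day 21 and of motor neuron genes (lower) at day 3 (camera adjusted p 0.0413, 0.0355 and 0.0434). Depth may have limited low-count genes.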

Other observations

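The test of day 21 replicate 2 against libraries of another day was chosen after its result was seen.

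Oligodendrocyte precursor genes did not pass the list test at day 3 (8 of 18 higher and 2 lower, or 10 and 2 adjusted over the list alone, median 0.40, camera adjusted p 0.439). They did not pass it at day 21 either (3 of 18 higher and 1 lower, median 0.046, camera adjusted p 0.834). The precursor receptor Gpr17 and the proteoglycan Cspg4 rose at day 3 (log2 fold changes 1.38 ± 0.14 and 1.17 ± 0.12, edgeR adjusted p 6.47e-05 and 5.23e-05). Genes of glucocorticoid and circadian response did not pass it either (5 of 17 higher and 4 lower, median 0.076, camera adjusted p 0.377 at day 3). Among them the cell cycle inhibitor Cdkn1a and the steroid-induced Fkbp5 rose at day 3 (log2 fold changes 2.49 ± 0.10 and 1.75 ± 0.12, edgeR adjusted p 2.12e-07 and 4.11e-06). Glycolysis genes moved both ways at day 3 (5 of 22 higher and 6 lower, or 5 and 7 adjusted over the list alone, median -0.017, camera adjusted p 0.638). Heat shock genes did not pass it at day 3 (6 of 13 higher and 3 lower, or 6 and 4 adjusted over the list alone, median 0.12, camera adjusted p 0.377).

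Proteoglycans of the perineuronal net did not pass the list test at day 3 (6 of 13 lower and 3 higher, median -0.29, camera adjusted p 0.217). Versican, Vcan, rose and the link protein Hapln4 fell (log2 fold changes 1.80 ± 0.26 and -1.56 ± 0.13, edgeR adjusted p 0.000471 and 1.39e-05). Homeostatic astrocyte genes did not pass it at day 21 (6 of 20 lower and 2 higher, median -0.24, camera adjusted p 0.0508). They were called lower without day 0 replicate 1, day 21 replicate 1 or day 3 replicate 2 or 3 (camera adjusted p 0.0288, 0.0375, 0.0406 and 0.0482), and with the length trend removed or no count filter (adjusted p over alternatives 0.00849 to 0.104). The water channel Aqp4 rose (log2 fold change 1.02 ± 0.21, edgeR adjusted p 0.00708). Adipocyte genes at day 21 passed the preset correlation only (4 of 6 higher, or 4 and 1 lower adjusted over the list alone, median 1.37, camera adjusted p 0.0468, adjusted p 0.149 with an estimated correlation). They lost the call without day 0 replicate 2 or day 21 replicate 2 (camera adjusted p 0.0504 and 0.0774) and with limma on log2 FPKM with 0.1 or 1 added (adjusted p over alternatives 0.0163 to 0.149). Erythroid genes summed to 22.3 ± 10.0, 35.6 ± 1.63 and 55.1 ± 36.1 FPKM (SD) on days 0, 3 and 21, with 96.8 in day 21 replicate 2. The nuclear RNA Malat1 stood at 30.6 ± 3.91, 47.1 ± 1.01 and 55.4 ± 14.6.

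Day 21 replicate 2 stood apart from the other day 21 libraries, with an SD across genes of 0.838 log2 units and 1777 genes more than 1 unit lower and 1117 higher. The difference correlated with gene length (Spearman rho -0.479 across genes, which are not independent) and with GC content (rho 0.294). A length trend alone was argued against, since the SD stayed at 0.762 with the trend removed, and so were length and GC trends together (SD 0.744). A library of another day was argued against too, since its correlation with its own group exceeded the highest other by 0.0187. Another difference in RNA quality, dissection or library preparation may be the source, and no biological explanation was tested.

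In fits of the 6 libraries of each comparison, the real grouping called 9966, 2909 and 3566 genes for day 3 against day 0, day 21 against day 0 and day 21 against day 3. The highest among other splits was 1, 1 and 0. In each comparison 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.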
